A study of Homo sapiens with 20 samples.

How the data were processed

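ATAC-seq libraries of LOVO and RKO cells were made with a commercial ATAC-seq library kit, per the labels. Trim Galore 0.6.6, Bowtie2 2.4.2, MACS2 2.2.7.1 and DiffBind 3.0.15 and the genome build hg38 are named, without roles or order, per the submitters' processing notes. How reads were shifted for the transposase, filtered or combined between the samples of a group is not given in the sources used here. The authors deposited 10 peak lists, 5 per line, named for groups. In 6 lists each interval carries a peak name of replicate 1 and the score of the deposited peak, whose MACS2 column is not stated; the scores ran from 1.75 to 51.1. In these lists up to 3.21% of the peak names stood on several intervals and the peak numbers ran past the number of intervals, as they would if the peaks of replicate 1 had been reduced to parts shared with another list, but that step is not stated. The other 4 lists (untreated shControl and untreated shMETTL3 of each line, called merged here after their names) hold intervals only. Untreated shControl thus has 2 lists per line, and which of them holds the samples labelled as a second batch is not given, so both were treated as 1 group. No other columns were used.

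Depth is unknown from peak lists, and a weaker library gives fewer peaks, so that a missing peak does not show closed chromatin. Precision is given for shares only, as 95% exact (Clopper-Pearson) binomial intervals, which cover counting error and neither the spread between samples nor that between lists. The pair of untreated shControl lists of each line was used as the only measure of spread, although it sets a merged list against a scored one and so mixes form with spread.

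Lists of the same form were compared, a choice made before the data were examined: shMETTL3 with shControl among the merged lists, olaparib with no treatment in shControl and shMETTL3 with shControl under olaparib among the scored lists, and, as a secondary comparison, olaparib with no treatment in shMETTL3 across the 2 forms. A peak counted as shared with at least 1 bp of overlap (bedtools 2.31.1). No count model, p-value or replicate-based error was computed, because no list is for a single sample and each group has 1 list, except untreated shControl, whose 2 lists per line differ in form. Chance overlap was measured with the second list moved along the chromosomes by 20 random offsets. Losses and gains in both lines were set beside the number expected if they were independent, over all regions and within 5 classes of width.

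Genes were taken from a table of the RefSeq annotation on GRCh38, the assembly that hg38 names, with 20037 protein-coding genes on chromosomes 1 to 22, X and Y. The table gives gene ends but neither strand nor exons, so windows of 1000 bp either side of both ends of each gene took the place of promoters, and exons, introns and UTRs were not told apart. At these windows lay 24.7 to 63.4% of the peaks of a list, against 5.38 to 7.63% at windows moved by 20 kb. A gene was called open when a peak overlapped either window. For 16 gene lists fixed before the data were examined (m6A machinery, homologous recombination, non-homologous end joining, poly(ADP-ribose) polymerases and base excision repair, mismatch repair, p53 targets, Wnt targets and regulators, intestinal epithelial identity, mesenchymal, leukocyte, neuronal, interferon response, L1 and retroelement control, chromatin remodelling and histone modification, DNA replication and cell cycle, and housekeeping), all 409 entries matched a symbol. The number of members lost or gained was ranked among 10000 random lists of genes with the same state in the reference list and, for losses, the same of 5 classes of covered bases. For gains the random lists were drawn from all closed genes, the 7097 without a gene-end peak in any list included. A high percentile of gains may therefore mark only genes that are often open. The percentile describes these lists of peaks and is not a test.

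Genes are named by a rule set before the data were examined: METTL3 in every list; list members that changed state in the same direction in both lines, up to 30 per comparison in list order; the 10 genes with the largest drop and the 10 with the largest increase in peaks assigned to them (nearest gene end within 50000 bp, ranked by the smaller change of the 2 lines, ties by symbol); epithelial, mesenchymal and mismatch repair genes open in all lists of one line and in none of the other; the widest peak of each list; and up to 4 members of each gene list per state. Some genes that the rule names are not reported here. Members named beyond 4, the intervals with the highest scores and the gene families in the closing part were chosen after their values were seen.

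The overlap and gene-list code was tested on simulated data. From the merged shControl lists, 13373 of 33474 peaks were dropped in LOVO and 11098 of 27978 in RKO, the rest were moved by up to 40 bp and 500 were added; the code found 13373 and 11091 lost and 500 gained in each. A planted list of 30 lost genes among 20037 came out at percentile 100 in both, and 4.00% of 400 random lists fell in the outer 5% in each. All planted genes were lost, and other open genes at random, without regard to covered bases or neighbours. These results check the code and not how the percentiles behave with real losses. The alternatives were a minimum overlap of 50% of the reference peak or of both peaks, the better 50% of each list by score or, where a list has none, width, lists of equal number, peaks within 500 bp joined, the other untreated control list, control regions in both control lists, and windows of 500 or 2500 bp. For lists of equal number only the longer list was cut, to its best peaks, and the shorter was kept whole. The gene-end windows, gene families, matching on width or score, the X chromosome comparison, the fate of lost peaks in the other lists and the kept share by score with the scored control list were added after the lists had been examined; of these, matching gene-end peaks on width and X-linked peaks on score were set down before their own results were seen. Motifs, repeat content and GC content need the genome sequence, which was not used here. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.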

Results

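Chromatin accessibility was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in LOVO and RKO, a pair of established human colon adenocarcinoma cell lines. Cells carried a control short hairpin RNA (shControl) or one against METTL3 (shMETTL3), the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) on RNA, and were untreated or given olaparib, an inhibitor of poly(ADP-ribose) polymerase. The series is about the removal of this mark from LINE1 RNA, the closing of chromatin and the response to blocked DNA repair. The labels list 20 samples: in each line 4 untreated shControl samples, 2 of them labelled as a second batch, and 2 samples each of untreated shMETTL3, shControl with olaparib and shMETTL3 with olaparib. The deposited files are 10 peak lists, 5 per line, each for a group and not for a sample. There are therefore no replicate values, no test between groups was possible, and the difference between the 2 untreated shControl lists of a line is the only measure of spread. The sequencing depth behind each list is unknown. Intervals given with shares are 95% exact binomial intervals and cover counting error only. A region is called kept when a peak of the other list overlaps it, lost when none does, and gained when a peak of the other list has no partner in the reference list.

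The lists differed widely in size. In LOVO the untreated shControl lists held 33474 peaks (the list of merged intervals) and 41431 peaks (the list with scores), untreated shMETTL3 held 16417, shControl with olaparib 32192 and shMETTL3 with olaparib 51462. In RKO the same lists held 27978, 21210, 6916, 25855 and 35455 peaks. They covered from 1.98 Mb in untreated RKO shMETTL3 to 21.6 Mb in the merged LOVO shControl list. Peaks within 1 kb of an annotated end of a protein-coding gene made up 27.4% of the merged shControl list and 37.1% of the untreated shMETTL3 list in LOVO, and 39.4% and 63.4% in RKO.

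**Figure D1:**
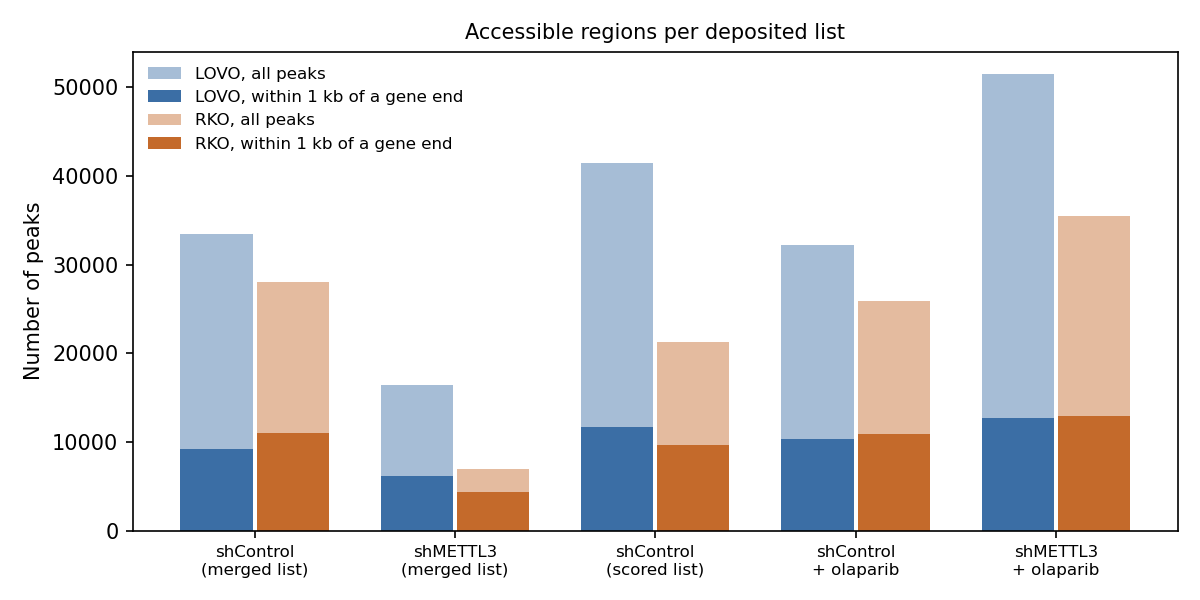
Number of peaks in each of the 10 deposited lists (vertical axis), with LOVO in blue and RKO in orange; pale bars are all peaks and dark bars are peaks within 1 kb of an end of a protein-coding gene. The untreated shMETTL3 lists are the shortest of each line (16417 and 6916 peaks) and the shMETTL3 lists with olaparib the longest (51462 and 35455 peaks).

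METTL3 itself lies on chromosome 14 from 21498138 to 21511340 (hg38), and a peak sat at its right-hand end in all 10 lists. In LOVO this peak spanned 21510850 to 21511607 (758 bp) in the merged shControl list and 21511075 to 21511590 (516 bp) in untreated shMETTL3. In RKO it spanned 21510808 to 21511575 (768 bp) and 21511275 to 21511527 (253 bp). A hairpin acts on the transcript, so the state of the gene's own chromatin does not check the knockdown.

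The 2 untreated shControl lists of a line were compared first, as the background for the other comparisons. They differ in form, with a median width of 571 bp in the merged and 288 bp in the scored list in LOVO and 429 and 297 bp in RKO, so that their difference mixes form with spread. Of the merged shControl peaks, 87.8% (87.4 to 88.1) in LOVO and 63.1% (62.6 to 63.7) in RKO had a partner in the scored shControl list. At gene ends the shares were 96.9% in LOVO and 78.1% in RKO. Of the protein-coding genes with an open end in the merged list, 319 of 10321 (3.09%) in LOVO and 1587 of 10993 (14.4%) in RKO had no gene-end peak in the scored list. Moved along the chromosomes to random places, the scored lists met at most 2.21% of the merged peaks in LOVO and 1.47% in RKO.

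Untreated shMETTL3 was compared with untreated shControl to ask how the peaks differed with the hairpin against the m6A writer. Both lines had far fewer peaks with shMETTL3, and nearly all of these lay on control peaks. Only 47.5% (47.0 to 48.0) of LOVO and 23.1% (22.6 to 23.6) of RKO shControl peaks were kept, while 97.3% and 95.7% of the shMETTL3 peaks lay on control peaks. With overlap of 50% of the control peak required, the RKO share was 5.87%. Kept RKO control peaks had a median width of 807 bp, and the shMETTL3 peaks that lay on control peaks 257 bp. Many partners were thus too narrow to cover 50%, so the 5.87% does not count absent peaks only. A gene-end peak was missing for 3225 of 10321 genes (31.2%, 30.4 to 32.2) in LOVO and for 5945 of 10993 genes (54.1%, 53.1 to 55.0) in RKO, among them LGR5, the receptor that marks intestinal stem cells, CCND1, which encodes cyclin D1, and the histone methyltransferase gene SETDB1. Only 79 genes in LOVO and 29 in RKO had a gene-end peak only with shMETTL3.

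Losses were less frequent at gene ends than elsewhere. In LOVO 66.0% of control peaks at gene ends were kept, against 40.8% within gene bodies and 40.3% between genes. In RKO the shares were 38.7%, 13.3% and 12.6%. The 2 control lists differed in the same way, with 96.9%, 84.2% and 84.4% kept in LOVO and 78.1%, 53.4% and 53.5% in RKO. Among peaks of like width, those at gene ends were kept with shMETTL3 2.501 points more often than others in LOVO and 5.54 points in RKO, and among peaks of like score 13.2 and 24.8 points. For olaparib in shControl the gap among peaks of like score was 13.9 points in LOVO and 11.2 in RKO. The kept share was larger for stronger peaks: with the scored shControl list as reference it was 4.42% in the lowest 10% of peaks by score and 94.7% in the highest 10% in LOVO, and 8.91% and 61.1% in RKO. Between the 2 lines, 1944 genes with an open end in both controls were lost in both, beside 1293 if the losses in RKO were independent of those in LOVO. The 1293 was not matched on covered bases and may be too low. Of 14766 LOVO control regions that were also open in the RKO control, 4851 were lost in both lines, beside 3707 if independent and 4160 if independent among regions of like width. With overlap of 50% of the control region required, 7428 were lost in both, beside 7129 and 7155. At that setting 13512 of the regions were lost in RKO and 7791 in LOVO. The number lost in both could therefore not lie far above independence, and this setting decides little about sharing.

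**Figure D2:**
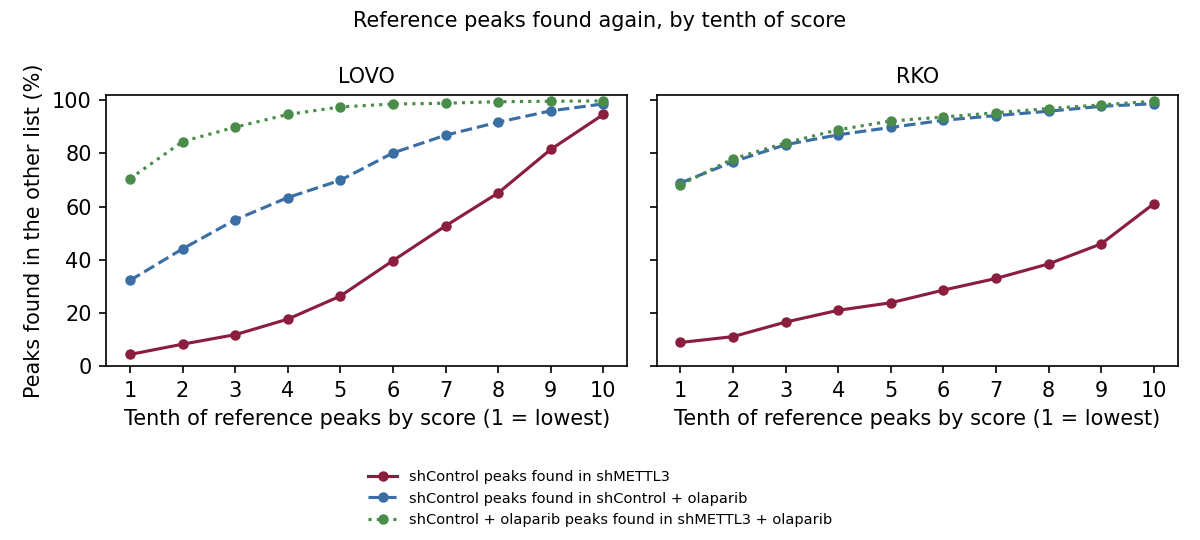
Share of reference peaks with a partner in the other list (vertical axis, percent) by class of the reference peaks, in 10 equal classes of the authors' score (horizontal axis, 1 lowest), in LOVO and RKO, for 3 comparisons. In class 1 4.42% (LOVO) and 8.91% (RKO) of scored shControl peaks were found with shMETTL3, and in class 10 94.7% and 61.1%.

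Wnt targets and regulators stood highest among the 16 gene lists relative to random lists. In LOVO 6 of 11 open members had no gene-end peak with shMETTL3 (percentile 95 among 10000 random lists matched on control state and covered bases), and in RKO 13 of 14 (percentile 99.7). LGR5, CCND1, NKD1, SP5, EPHB3 and CTNNB1, the gene for beta-catenin, were lost in both lines. AXIN2, RNF43 and ZNRF3, 3 inhibitors of the pathway, were lost in RKO. The RKO controls also differed in this list: 7 of 14 members open in the merged list were closed in the scored list (percentile 99.8). With the scored control list as reference, 10 of 15 members were lost in LOVO (percentile 99.4) and 7 of 8 in RKO (percentile 98.7), but LGR5, CCND1, NKD1, SP5, AXIN2 and ZNRF3 were then closed in RKO before and after.

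DNA repair genes lost gene-end peaks about as often as matched random lists, or less often. For homologous recombination, 7 of 35 open members were lost in LOVO (percentile 23.3) and 16 of 38 in RKO (percentile 14.2); RAD51AP1, RAD54L, DNA2, GEN1 and TOPBP1 were lost in both lines, and BRCA2, RAD50 and ATR in RKO. Non-homologous end joining lost 2 of 16 members in LOVO (percentile 6.34) and 10 of 19 in RKO (percentile 58.9), with LIG4, the ligase of that pathway, in both. In the list of poly(ADP-ribose) polymerases and base excision repair, 4 of 24 were lost in LOVO (percentile 7.93) and 8 of 26 in RKO (percentile 1.28); HPF1, the cofactor of serine ADP-ribosylation, and the glycosylase gene NEIL3 were lost in both, and PARP1 kept its peak in both. Mismatch repair lost 1 of 9 members in LOVO (RFC1) and 4 of 8 in RKO (percentile 48.4), RFC1 among them.

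The m6A genes themselves lost 5 of 21 open members in LOVO (percentile 24.1) and 10 of 23 in RKO (percentile 10.9), with the methyltransferase genes ZCCHC4 and PCIF1 and the reader genes IGF2BP2 and HNRNPA2B1 in both. Genes for L1 and retroelement control lost 9 of 23 in LOVO (percentile 82.8) and 15 of 24 in RKO (percentile 67.2); SETDB1, its partner ATF7IP and the maintenance DNA methyltransferase gene DNMT1 were lost in both lines. p53 targets lost 5 of 23 in LOVO (percentile 33.8) and 6 of 25 in RKO (percentile 0.355), with BAX and ZMAT3 in both lines, while MDM2 and GADD45A kept their peaks in both, and CDKN1A, closed in the merged control of either line, had one with shMETTL3 in RKO. DNA replication and cell cycle genes lost 4 of 31 in LOVO (percentile 2.23) and 12 of 31 in RKO (percentile 8.04), with CCNA2, AURKB, PLK1 and BUB1, which act in mitosis or at its entry, in both. Chromatin remodelling and histone modification lost 8 of 31 and 16 of 34 (percentiles 47.8 and 27.3), interferon response 7 of 25 and 11 of 19 (percentiles 30.2 and 44.0; MAVS and RSAD2 in both), and housekeeping 5 of 16 and 6 of 20 (percentiles 52.0 and 2.55).

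Tissue lists had fewer open members. Intestinal epithelial identity lost 4 of 14 in LOVO (percentile 24.3), among them VIL1, HNF4G and CEACAM5, and 5 of 6 in RKO (percentile 82.5), CDX2, KRT18, EPCAM, HNF4G and CLDN3. Mesenchymal genes lost 5 of 9 and 4 of 7 (percentiles 82.7 and 54.2), leukocyte genes 1 of 3 and 3 of 5 with SPI1 in both, and neuronal genes 3 of 5 and 3 of 4 with SYP and DLX2 in both. Of the 45 list members lost in both lines, 31 were also lost in both with the scored control list as reference. Of those named here, TOPBP1 was closed in LOVO in that control and with shMETTL3, as were LIG4, ZCCHC4, IGF2BP2, ATF7IP and SYP in RKO, beside the Wnt genes already given. The 10 genes with the largest drop in the number of peaks nearest to them were MYH9, a non-muscle myosin heavy chain gene on chromosome 22 (8 to 2 in LOVO and 8 to 1 in RKO), the transcription factor gene NFIA (9 to 2 and 6 to 0), SVIL (8 to 2 and 8 to 1), ADGRE5, IGF2BP2 (8 to 3 and 6 to 1), SH3RF1, TRA2B, ADCY9, ANKRD55 and ATP9A. No gene had more than 1 extra peak in both lines; by symbol the list of such genes began with ACTMAP, ADAT3, ANKRD34A, ATG9A, C2orf76, C3orf38, CCDC191, CEP95, CFAP157 and CHPF. With the control list cut to its widest peaks, as many as the whole shMETTL3 list holds, the kept share was 67.8% in LOVO and 53.2% in RKO. In these lists 2424 and 2927 genes were lost and 467 and 1345 gained, beside 79 and 29 gained in the full lists. Cutting only the control list can add gains but not losses, so these counts follow partly from the cut.

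**Figure D3:**
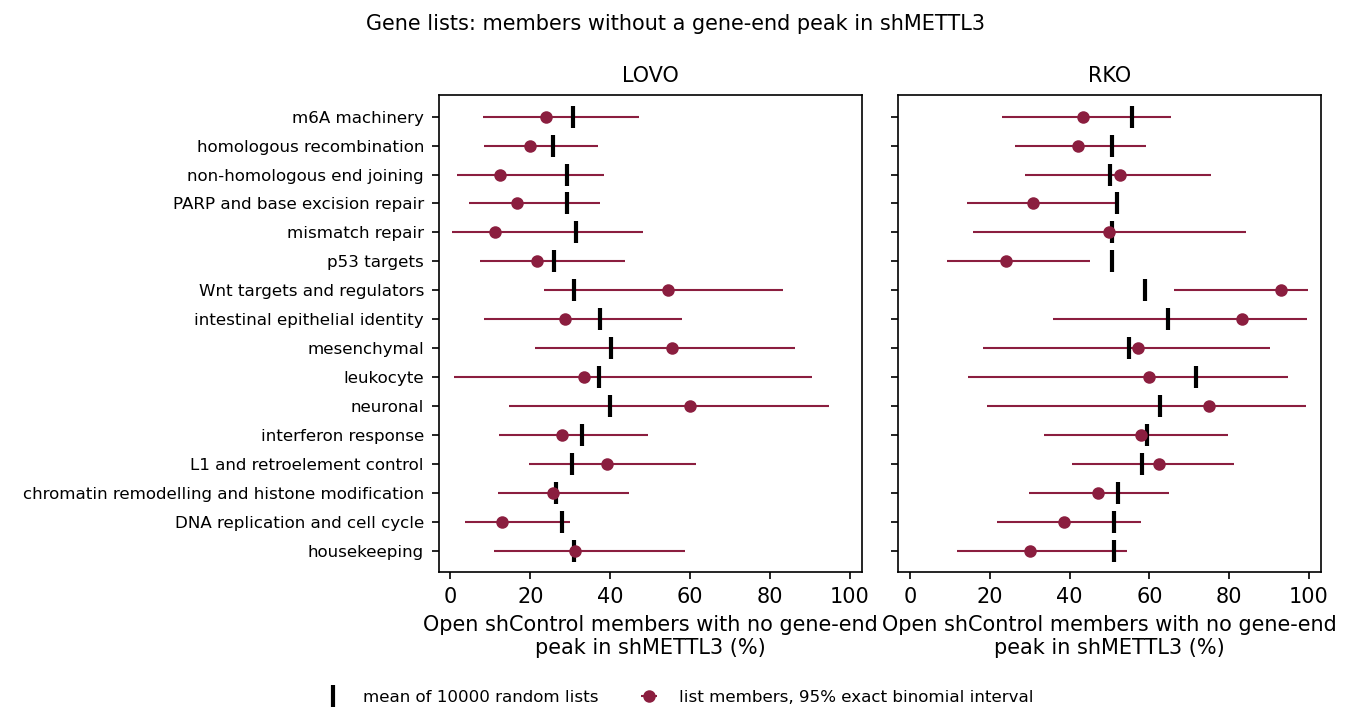
Share of the members of each gene list open in merged shControl that had no gene-end peak in untreated shMETTL3 (horizontal axis, percent), in LOVO and RKO; points carry 95% exact binomial intervals and black ticks are the mean of 10000 matched random lists. Wnt targets and regulators lie to the right of their ticks in both lines (6 of 11 and 13 of 14 lost).

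Olaparib was compared with no treatment in shControl cells to ask what the drug alone did to accessibility. The lines went in opposite directions: LOVO had 0.777 times as many peaks with olaparib (41431 to 32192) and RKO 1.22 times as many (21210 to 25855). In LOVO 71.8% (71.4 to 72.3) of the untreated peaks were kept and 9.19% of the olaparib peaks were gained, and in RKO 88.5% (88.1 to 88.9) were kept and 29.2% gained. LOVO lost the gene-end peak of 836 of 11188 genes (7.47%) and gained 309, while RKO lost 225 of 9542 (2.36%) and gained 1168. These counts depended on which untreated list was used: with the merged list as reference, RKO had 0.924 times as many peaks with olaparib, 778 genes lost and 270 gained, and LOVO had 557 lost and 897 gained. In lists of equal number the gene counts turned too, to 406 lost and 1173 gained in LOVO and 927 and 691 in RKO. There the untreated list was cut in LOVO and the olaparib list in RKO, which by construction adds gains in LOVO and losses in RKO.

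Few genes changed state in the same direction in both lines: 55 were gained, beside 7.14 if independent, and 31 were lost, beside 5.41. The 7.14 was taken over 8265 genes closed in both references, the 7097 without a gene-end peak in any list included. It is therefore too low as a background, and the 55 do not show that gains were shared. The 5.41 for losses was not matched on covered bases. Among regions, matching on width raised the losses in both lines if independent from 113 to 221, beside 318 seen. The 5.41 may thus be too low as well. Among list members the gains included SNAI1, which drives epithelial to mesenchymal transition, and the Polycomb genes SUZ12 and EED. Of chromatin remodelling and histone modification genes closed in untreated shControl, 4 of 7 were open with olaparib in LOVO (SMARCA4, SUZ12 and EED among them) and 8 of 11 in RKO (among them SMARCB1, KMT2A, SUZ12 and EED), at percentile 100 of random lists in both lines. The housekeeping list did the same in RKO, with 4 of 4, and between the LOVO controls 5 of the 9 chromatin genes closed in the merged list were open in the scored list (percentile 99.9). Random lists for gains were not matched on covered bases. In RKO proteasome subunit genes stood at percentile 99.6 of gains with olaparib and olfactory receptor genes at 0. The percentile of 100 therefore does not set chromatin genes apart from other often open genes. SNAI1, SUZ12 and EED were not gained in both lines with the merged control list as reference, since SNAI1 and EED were open in it in both lines and SUZ12 in RKO.

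Few repair genes were lost, and in LOVO about as few as in matched random lists. No member of the homologous recombination, non-homologous end joining, base excision repair, mismatch repair or p53 target lists lost its gene-end peak in LOVO, out of 37, 17, 25, 9 and 25 (percentiles 12.8, 32.5, 22.8, 32.3 and 21.5), and 1 each of homologous recombination (FANCM), mismatch repair (RFC1) and p53 targets (BBC3) did in RKO, out of 36, 7 and 24 (percentiles 66.3, 98.7 and 80.4). The Wnt genes LGR5 and CCND1 were lost in LOVO, and AXIN2, LEF1 and SP5 gained in RKO, where all 3 were open in the merged untreated list. The largest drop in assigned peaks in both lines was at PHLDA1 (11 to 8 in LOVO and 7 to 4 in RKO), followed by DENND2A, EARS2, EDC4, EEIG1, EVA1C, GNA13, INF2, LIMD1 and MED29, and the largest increases were at RTKN2 (3 to 6 and 1 to 4), ASXL2 (3 to 5 and 2 to 4) and SRBD1 (4 to 6 and 0 to 2). The remaining 7 of the 10, ABCC3, ABHD6, ACTA2, ACTL9, ACVR2B, AGO4 and ANGEL1, had 1 more peak in each line.

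With olaparib, shMETTL3 was compared with shControl to ask whether the difference between the hairpins was the same under the drug. Here shMETTL3 had more peaks than shControl in both lines, 1.60 times as many in LOVO and 1.37 times as many in RKO. The covered length was 1.37 and 1.16 times as large. For comparison, the scored untreated control list held 1.24 times as many peaks as the merged one in LOVO and 0.758 times as many in RKO. Of the shControl peaks 93.4% (93.1 to 93.6) in LOVO and 89.5% (89.2 to 89.9) in RKO were kept, and 40.5% and 33.1% of the shMETTL3 peaks were gained. In LOVO 1212 genes gained and 160 lost a gene-end peak, and in RKO 800 gained and 188 lost. Between the 2 untreated control lists, which differ in form, 1186 genes were gained and 319 lost in LOVO, and 136 gained and 1587 lost in RKO. Changes of this size thus also arose between control lists, although in opposite directions in the 2 lines. LGR5, CCND1, the Fanconi anaemia gene FANCM and SNAP25 were gained in both lines.

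Of 20595 regions open in both shMETTL3 lists with olaparib, 1784 were gained in both lines, beside 1497 if independent among regions of like width. Of 8295 genes closed in both shControl lists with olaparib, 163 were gained in both lines, beside 31.6 if independent. These genes include the 7097 without a gene-end peak in any list, which makes 31.6 too low as a background. The gene count therefore does not show that gains were shared. Gained regions lay mostly away from gene ends, with 12.2% of them at gene ends in LOVO and 18.7% in RKO, against 33.0% and 44.5% of kept regions. The same held between the 2 untreated control lists, with 17.7% and 17.1% of gained and 30.2% and 48.7% of kept peaks at gene ends. Of Wnt genes closed in shControl with olaparib, 2 of 8 in LOVO (LGR5 and CCND1, percentile 82.8) and 5 of 11 in RKO (LGR5, CCND1, NKD1, ZNRF3 and EPHB2, percentile 99.9) were open with shMETTL3. In LOVO CDX1, KRT20, CDH1 and ST14 of the intestinal list were gained (4 of 11, percentile 97.3), and in RKO the repair gene PARG and the p53 targets CDKN1A and BBC3. As random lists for gains were not matched on covered bases, these percentiles do not set the lists apart from other often open genes. At CCND1 the gained LOVO peaks included one at the gene's left-hand end, on chromosome 11 from 69640985 to 69641329, with a score of 8.14, whereas the RKO peak lay at the other end, from 69654666 to 69654888, with a score of 3.30.

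Losses in this comparison were few. SUZ12 was the only list member lost in both lines; its peaks in shControl with olaparib had low scores, 3.82 in LOVO and 5.69 in RKO, and lay at different places beside the gene's left-hand end, and reads from related sequences elsewhere were not told apart here. The largest increases in assigned peaks, equal to each other, were at RASA3, a Ras GTPase-activating protein gene on chromosome 13 (1 to 6 in LOVO and 2 to 7 in RKO), and the ubiquitin ligase gene SMURF2 (6 to 11 and 11 to 16). They were followed by ATP9A (4 to 8 and 5 to 9), B4GALT5, C13orf42, ERGIC1, HNF4A (5 to 9 and 0 to 4), LOC124905135, the receptor tyrosine kinase gene MET (9 to 13 and 4 to 8) and NUP50 (1 to 7 and 0 to 4). No gene had over 1 peak fewer in both lines, and by symbol such genes began with ABCC3, ACAA1, ADGRD1, ANKRD34A, ARFGEF2, ATP6V1E1, BCL11A, BICC1, C3orf80 and CAVIN2. When the shMETTL3 list was cut to the number of peaks of the shControl list, by highest score, more genes were lost than gained. The counts were 1633 against 385 in LOVO and 1566 against 350 in RKO. The shControl list was kept whole, weak peaks included, so the cut adds losses by construction and does not show a reversal.

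In shMETTL3 cells, olaparib was compared with no treatment as a secondary comparison, since the untreated list gives merged intervals and the treated list scored ones. The labels name a second batch for untreated shControl only and give no batch for the olaparib samples. Treated and untreated samples may therefore differ in batch as well. With 1 bp of overlap, and treated lists 3.13 and 5.13 times as long, 99.2% of the untreated peaks in LOVO and 97.2% in RKO were kept, and 67.0% and 81.2% of the olaparib peaks were gained. The RKO share kept was 47.8% with overlap of 50% of both peaks and 55.3% in lists of equal number. A gene-end peak appeared at 4558 genes in LOVO and 6040 in RKO and disappeared at 20 in each. Of the genes that untreated shMETTL3 lacked relative to shControl, 3046 of 3225 (94.4%, 93.6 to 95.2) in LOVO and 5555 of 5945 (93.4%, 92.8 to 94.1) in RKO were open in shMETTL3 with olaparib. The same genes were open in the scored untreated shControl list for 90.9% in LOVO and 76.1% in RKO, and in shControl with olaparib for 84.7% and 87.4%.

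LOVO and RKO differed at epithelial genes in every list. The intestinal epithelial genes KRT19, GPA33, LGALS4, HNF4A, GUCY2C and ELF3 were open in all 5 LOVO lists and in no RKO list, and HNF4A, a transcription factor of the intestine and liver, had peaks at both ends. No member of the mesenchymal list was open in all lists of one line only. Among all 20037 protein-coding genes, 264 were open in all 5 LOVO lists and in no RKO list, and 63 in all 5 RKO lists and in no LOVO list. A further 4025 were open in all 10 lists and 7097 in none, and the rest were mixed. The shortest list limits these counts: untreated shMETTL3 had 7175 open genes in LOVO and 5077 in RKO. The difference between 264 and 63 therefore partly follows list length. Of the merged LOVO shControl peaks 44.1% (43.6 to 44.6) had a partner in the RKO list of the same kind, and 54.6% (54.0 to 55.2) in the other direction.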

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

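The tests on the difference between the 2 control lists, the matching of gene-end peaks on score and the use of intervals for the X-linked peaks were chosen after the results they bear on had been seen.

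The number of peaks differed between shMETTL3 and shControl in opposite directions without and with olaparib. Without the drug shMETTL3 had 0.490 times as many peaks as shControl in LOVO and 0.247 times as many in RKO, and with it 1.60 and 1.37 times as many. Olaparib itself went with 0.777 times as many peaks in LOVO shControl, 1.22 times as many in RKO shControl (0.924 with the merged control list), and 3.13 and 5.13 times as many in LOVO and RKO shMETTL3, where an untreated merged list is set against a treated scored one. With lists of groups and not of samples, none of these differences between lines or treatments was tested. As the labels give no batch for the olaparib samples, drug and batch cannot be told apart.

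For the fewer peaks in untreated shMETTL3, the share of merged shControl peaks found in the other shControl list exceeded the share found in shMETTL3 by 40.3 points in LOVO and 40.04 points in RKO, but a list 0.490 or 0.247 times as long can hold few more of those peaks than it did, so that the gap decides nothing about a difference like that between control lists. In lists of equal number the shares were 78.8% (controls) and 67.8% (shMETTL3) in LOVO, and 73.2% and 53.2% in RKO. The control pair differs in form and in the number of peaks compared, so that these shares do not settle it either. Weaker libraries in which the weakest peaks go first stay open: of the 10% of scored shControl peaks with the highest score, 94.7% were found in LOVO, as that would need, and 61.1% in RKO, which lies between the bounds set for and against it. A loss concentrated away from gene ends also stays open, since gene-end peaks were kept 2.501 and 5.54 points more often than others of the same width (LOVO and RKO), under the bound of 5 set against it in LOVO, but 13.2 and 24.8 points more often than others of the same score, so that the width bound alone was too narrow a test. The score-matched gap was also 13.9 and 11.2 points for olaparib in shControl, and 2.23 and 9.82 for shMETTL3 under olaparib. In LOVO it was thus no wider for shMETTL3 than for olaparib in shControl. The width-matched gap between the control lists was 1.67 and -0.810 points. Lower accessibility after METTL3 depletion, the biological explanation that the design names, may hold as well and cannot be told apart from a weaker library without read counts. The 94.4% and 93.4% of lost genes that were open in shMETTL3 with olaparib bear on neither, as the treated libraries are others.

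For the larger number of peaks in shMETTL3 with olaparib, peaks split into more pieces are argued against, as the ratio to shControl with olaparib was 1.55 in LOVO and 1.34 in RKO with peaks within 500 bp joined. Additional weak peaks stay open: 76.2% of the gained LOVO peaks and 70.9% of the gained RKO peaks lay in the lower 50% of the list by score, between the bounds set for and against it. A difference like that between the 2 untreated control lists, with ratios of 1.24 in LOVO and 0.758 in RKO, also stays open. An effect of METTL3 depletion under the drug stays open too and was not tested.

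X-linked peaks were missing from untreated shMETTL3 more often than autosomal ones: 32.9% (29.4 to 36.5) of 699 X-linked shControl peaks were kept in LOVO and 13.0% (10.7 to 15.6) of 753 in RKO, against 47.8% and 23.4% of autosomal peaks. In LOVO the gap to the autosomes was 16.2 points wider than between the 2 control lists. That control pair kept 89.0% of X-linked and 87.7% of autosomal peaks, which left less room for a gap than the shorter shMETTL3 list. X-linked peaks were, however, kept 1.25 points more often there, and 0.984 points with width matched (interval -1.57 to 3.21). For olaparib in LOVO shControl, X minus autosomes was -1.05 points with 71.9% of autosomal peaks kept. These values argue against a difference of that kind in LOVO, as far as 1 control pair that differs in form can. In RKO the gap was only 0.754 points wider, so that it may be one like that between the 2 control lists. Other RKO comparisons had smaller gaps, with X minus autosomes -4.84 points for olaparib in shControl and -3.54 points for shMETTL3 under olaparib. With the score matched in the scored shControl list, the share of X-linked peaks found differed from the autosomal share by -7.06 points in LOVO (interval -10.1 to -3.87) and -8.23 points in RKO (interval -11.6 to -4.48). Both values lie past the bound of -5 points set against lower scores as the cause, but both intervals hold it, which leaves lower scores open. No biological explanation was tested.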

How the results depend on the processing

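Gene ends took the place of transcription start sites after the data were seen; the settings below, window widths and the other control list included, were planned. No paired analysis was possible because each list stands for a group and carries no sample, and for the same reason leave-one-out was not possible. Motif, repeat and GC comparisons were not run. The fewer peaks in untreated shMETTL3 and the more in shMETTL3 with olaparib kept their direction under joining and, for the former, with either control list. The cause of the differences below was not tested, except where lists of equal number by construction take away a difference in number.

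Kept shares are given in percent for LOVO and RKO. With overlap of 50% of the reference peak they were 58.2 and 41.8 between controls, 37.7 and 5.87 for shMETTL3, 68.1 and 85.9 for olaparib in shControl, 87.6 and 83.1 for shMETTL3 under olaparib, 93.0 and 93.7 for olaparib in shMETTL3, and 38.2 for LOVO in RKO. With that overlap of both peaks they were 58.2 and 41.5, 37.7 and 5.84, 63.1 and 73.3, 82.2 and 78.8, 90.8 and 47.8, and 37.0. With the better 50% of each list they were 81.8 (LOVO controls), 46.1 (LOVO shMETTL3), 69.4 and 81.1, 90.4 and 84.4, 97.4 and 96.4, and 54.2. In lists of equal number they were 78.8 and 73.2, 67.8 and 53.2, 80.9 and 79.7, 74.9 and 74.1, 68.0 and 55.3, and 48.2. With peaks within 500 bp joined they were 64.6 (RKO controls), 24.1 (RKO shMETTL3), 72.5 (LOVO olaparib in shControl), and 93.7 and 90.2 (shMETTL3 under olaparib). With the other control list they were 40.2 and 28.9 for shMETTL3 and 77.0 and 73.1 for olaparib, and in regions of both control lists 53.4 and 34.8, and 83.0 and 93.1.

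Ratios of peak numbers with peaks joined were 1.18 (LOVO controls), 0.795 (LOVO olaparib in shControl), 1.55 and 1.34 (shMETTL3 under olaparib), and 2.96 and 4.83 (olaparib in shMETTL3). With the other control list they were 0.396 and 0.326 for shMETTL3 and 0.962 for olaparib in LOVO, and for olaparib in RKO the direction reversed, to 0.924.

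Regions changed in both lines, with overlap of 50%, numbered 7428 lost and 617 gained for shMETTL3, 408 gained for olaparib in shControl, and 290 lost for shMETTL3 under olaparib, beside 4851, 6, 233 and 64 with 1 bp. If independent they would number 7129, 571, 201 and 120 with 50%, and 3707, 0.146, 86.3 and 13.5 with 1 bp. With 50%, a peak that covers less than that share of the reference peak counts as gained, although it has a partner with 1 bp. For shMETTL3 3380 of 4396 regions were gained in RKO by that rule, beside 23 with 1 bp. In lists of equal number, 467 genes were gained in LOVO and 2927 lost and 1345 gained in RKO for shMETTL3, beside 79, 5945 and 29. For olaparib in shControl 406 were lost and 1173 gained in LOVO, and 927 and 691 in RKO, beside 836, 309, 225 and 1168. For shMETTL3 under olaparib 1633 were lost and 385 gained in LOVO, and 1566 and 350 in RKO, beside 160, 1212, 188 and 800. With the other control list 34 genes were gained in LOVO and 189 in RKO for shMETTL3, and for olaparib 557 were lost and 897 gained in LOVO and 778 and 270 in RKO. Only the longer list was cut in lists of equal number, which adds gains where that is the reference and losses where it is the other list. The depth behind each list is unknown, so a setting that removes weak peaks does not make the lists alike in depth. Windows of 500 and 2500 bp left all these gene counts within 1.5 times.

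Of the counts of list members lost, 80 of 96 stayed within 1.5 times with windows of 2500 bp, 79 of 96 with 500 bp, 42 of 96 in lists of equal number (34 higher, 30 lower, the rest equal), and 47 of 64 with the other control list. Of the counts gained, 75, 76, 40 and 31 did. The share of peaks at gene ends was larger with windows of 2500 bp in all 10 lists, as wider windows must give.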

Other observations

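All tests on gene families and the recurrent intervals were chosen after the data were seen.

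Histone genes lost gene-end peaks in untreated shMETTL3 more often than matched random genes. In LOVO 30 of 46 open members had no gene-end peak with shMETTL3 (13.7 on average in random lists, percentile 100) and in RKO 38 of 56 (29.0 on average, percentile 99.4), while between the 2 control lists 0 of 46 and 7 of 56 were lost. Between the same control lists 16 of 38 closed histone genes were gained in LOVO (percentile 100) and 0 of 28 in RKO. Olaparib in shControl lost 9 of 62 in LOVO (percentile 97.7) and 2 of 49 in RKO (percentile 94.5), and shMETTL3 under olaparib 0 of 54 and 0 of 51. The family thus also changed between lists without the METTL3 hairpin. Histone genes lie in clusters, and neighbours share windows, so members are not independent. HOX genes lost 11 of 16 in LOVO (percentile 98.3) and 16 of 21 in RKO (percentile 72.6), but 11 of 21 also between the RKO controls (percentile 99.1). Zinc finger genes with ZNF symbols lost 93 of 292 in LOVO (percentile 32.8) and 169 of 363 in RKO (percentile 0.095, and 0.705 between the RKO controls). Genes for ribosomal proteins lost 19 of 76 and 49 of 83 (percentiles 6.80 and 80.3), those for mitochondrial ribosomal proteins 21 of 67 and 45 of 73 (percentiles 70.7 and 91.8), and those for proteasome subunits 10 of 37 and 21 of 37 (percentiles 14.8 and 63.1).

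Of the interferon list, OAS1 and OASL and the nucleotide sensor gene STING1 had a gene-end peak in all 5 LOVO lists and in no RKO list. Of the neuronal list, SYT1 was open in all LOVO lists only and GRIN1 in all RKO lists only.

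The widest peaks were 2737 bp in merged LOVO shControl (chromosome 12, 52925000 to 52927736, in the body of a gene near KRT18), 1797 bp in untreated LOVO shMETTL3 (chromosome 7, at an end of KMT2E), 2771 bp in merged RKO shControl (chromosome 1, between genes near TNFRSF14) and 1226 bp in untreated RKO shMETTL3 (chromosome 8, at an end of LOC124902042). In the scored lists they were 3066 bp in LOVO shControl, 1700 bp in LOVO shControl with olaparib and 3151 bp in LOVO shMETTL3 with olaparib, all on chromosome 21 from about the same start (6369267, 6369257 and 6369257) with no protein-coding gene end within 50000 bp. In RKO they were 2113 bp in shControl (chromosome 11, at an end of FOSL1), 2067 bp in shControl with olaparib (chromosome 8, at an end of ZHX1-C8orf76) and 2395 bp in shMETTL3 with olaparib (chromosome 21, starting at 6369065).

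The same 3 intervals held the 3 highest scores in all 6 scored lists, and each had a peak in the other 4 lists too. They lie on chromosome 20 from 14609938 to 14610165, chromosome 5 from 74758884 to 74759077 and chromosome 17 from 22521263 to 22521553, with scores of 50.7, 45.5 and 29.8 in LOVO shControl. The first ranked highest in every scored list.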
